A study of Mus musculus with 12 samples.

How the data were processed

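Forebrain tissue of mouse embryos at embryonic day 12.5 was profiled in 2 genotypes, wild type and a genotype that the labels call EedcKO, named for Eed, a core subunit of Polycomb repressive complex 2 (PRC2). Per the labels, Eed and its input were measured by cross-linked chromatin immunoprecipitation (X-ChIP), and histone H3 lysine 27 trimethylation (H3K27me3), lysine 27 acetylation (H3K27ac), RNA polymerase II (RNA-Pol2) and an IgG control by CUT&Tag, in which a tethered transposase cuts the DNA next to the antibody. Per the labels' protocols, the Eed libraries were sequenced on the BGISEQ-500 and the CUT&Tag libraries on the NovaSeq platform. There was 1 library for each genotype and target, 12 libraries in all, so no difference has a replicate check and no p-value is given. The sex of the embryos, the number of embryos behind a library and the deleted part of Eed are not given in the sources used here.

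Per the submitters' processing notes, the tools named were Bowtie2 2.4.1, MACS2 2.2.7.1, deepTools 3.4.0 and ChIPseeker 1.22.1, with the genome build mm10; filters on mapping quality and duplicates are not given in the sources used here. The deposited promoter tables hold whole-number read counts for 55385 windows, each with an Ensembl identifier, a symbol and a strand; all but 2 windows span 2 kb centred on an annotated transcription start site. The authors named these tables for RPKM, but the values are whole numbers whose totals differ between libraries, and they were therefore treated as counts. The deposited summit lists of the 8 antibody libraries give 1 position per peak, called in each library by itself, with a score of the form −log10 of a p-value or q-value; which of both it is is not stated. This score is the authors' and was used only to filter summits within a list. In the table of the library labelled EedcKO H3K27ac, 27 symbols had turned into spreadsheet dates, and symbols were taken by Ensembl identifier from the other tables. Of the symbols, 38986 matched the RefSeq gene table of assembly GRCm38.p6, which was used only for gene type and for older symbols of the histone genes.

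The plan fixed before the data were examined assumed RPKM. Counts were converted to RPKM with the window length in kb and the library's total promoter count, and the planned rules were kept. For each of 55276 symbols the window with the highest mean RPKM over the 8 antibody libraries was used. The log2 ratio of EedcKO to wild type was taken with a pseudocount of 0.5 RPKM among promoters with a mean of at least 1 RPKM over both libraries, and an absolute log2 ratio of at least 1 was the size rule. Ratios near the pseudocount understate the change of low promoters. Scaled by library totals, the median promoter moved by 0.88 for Eed, 0.85 for H3K27me3, -1.04 for H3K27ac and -0.41 for RNA-Pol2 on the log2 scale; the cause was not tested. With both libraries scaled to the same median over all windows, the median ratio of the tested promoters was -0.58 for Eed and 0.20 for RNA-Pol2 and within 0.01 of 0 for the histone marks. Ratios of genes and gene lists are therefore given relative to this median, as relative log2 ratios, which the plan had not foreseen. Control libraries, input for Eed and IgG for the other targets, are given beside them.

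Polycomb promoters were the 1000 genes with the highest mean over both genotypes of the log2 ratio of H3K27me3 to IgG, with the EedcKO library as labelled, compared with all other promoters with a mean of at least 0.1 RPKM. The median log2 ratio of each of 23 gene lists fixed before the data were examined was set against 10000 random lists of the same size, matched in 50 bins on the mean RPKM of the target. A second percentile, matched on the mean RPKM of the control libraries, was chosen after the data were seen, because matching on a mark that changes strongly fills the random lists with the same genes. Genes are not replicates, and these percentiles describe the libraries only. Named genes followed a rule fixed beforehand: the 10 largest increases and the 10 largest decreases among protein-coding named genes (without Gm and Rik models and Mir genes) whose higher library had at least 2 times the RPKM of its control, both with the pseudocount added, and up to 4 members of each list with the largest change under the same filter. This filter depends on the change, so the genes it passes are not used to count directions. The Eed gene is named in every library.

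Intervals of single genes are exact 95% Clopper-Pearson intervals of the ratio of both counts, shifted by the same median. They cover counting error only, since reads without molecular identifiers are not independent molecules. A count of 0 was read as up to 3 counts per library, and a fold against it is a lower bound, relative to the median promoter. Intervals of list medians are order-statistic intervals across genes, and intervals of shares are Wilson intervals. The totals of the promoter counts, from 948955 to 3842779, are not the sequencing depth of the libraries, since reads outside the windows were not in the tables. At these totals, 1 read in a 2 kb window was worth from 0.130 to 0.527 RPKM.

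Summits were called shared when they lay within 500 bp of each other and at a promoter when they lay within 1 kb of a window's centre; 100 random shifts of the summits along each chromosome gave the share by chance. A broad domain has few summits, so a promoter inside it can be without one. The relation between targets is the Pearson correlation of the log2 ratios across genes, with Spearman's beside it. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. They were tested on simulated data: with 200 promoters changed 4-fold, the size rule recovered 99.5% for Eed, 98.0% for H3K27me3, 99.5% for H3K27ac and 100% for RNA-Pol2, and it called 3.78%, 1.87%, 1.84% and 0.649% of the unchanged promoters. The simulation covers counting error, not the spread between animals.

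The alternatives tried were other pseudocounts, other filters, scaling to the same median, subtraction of the control library, other Polycomb sets, other summit distances and scores, and autosomes only. Those chosen after the data were seen were a minimum of 20 reads, a counting interval that excludes no change, the second set of random lists and the comparison of H3K27me3 and H3K27ac, gene lists included, with the EedcKO library of the other label. GC content was not checked, since no genome sequence was used here. Reads shared between near-identical genes, such as the olfactory receptor, Serpina1 and Zfp families, can be placed differently in each library, and values of these genes are uncertain.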

Results

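Chromatin of the embryonic mouse forebrain was mapped in wild type and EedcKO embryos to set the binding of Eed beside the histone marks H3K27me3 and H3K27ac and the occupancy of RNA-Pol2. Eed is the PRC2 subunit that binds H3K27me3 and is needed for the complex to methylate. H3K27me3 is the mark of Polycomb repression, H3K27ac marks active promoters and enhancers, and RNA-Pol2 marks transcribed genes. Each genotype had 1 library of each of the 4 targets, 1 input library for Eed and 1 IgG library for the other targets. Every difference is therefore between 2 libraries and has no replicate check. Total promoter counts in wild type and EedcKO were 1972842 and 1446764 for Eed, 3161526 and 1689129 for H3K27me3, and 1944323 and 3628039 for H3K27ac. They were 2482297 and 3842779 for RNA-Pol2, 1018763 and 948955 for input, and 1412310 and 1564905 for IgG. Coordinates are those of mm10.

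The Eed promoter window (chromosome 7, 89979983 to 89981982) held 121 counts in the wild type Eed library and 40 in the EedcKO Eed library, beside 27 and 19 in input. In RNA-Pol2 it held 89 and 246 counts, in H3K27ac 130 and 35, in H3K27me3 31 and 79, and in IgG 20 and 50. The deleted part of Eed is not given, and these counts do not test the genotype.

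In the wild type forebrain, H3K27me3 and H3K27ac lay at different gene lists. The 39 Hox promoters, which pattern the body axis behind the forebrain, had a median of 1384 H3K27me3 counts and 18 H3K27ac counts. The 45 ribosomal protein genes had 39 H3K27me3 and 91 H3K27ac counts, and 30 of them had an H3K27ac summit at a promoter against 3 with an H3K27me3 summit and 12 with an RNA-Pol2 summit. Of 20 housekeeping genes 8 had an H3K27ac and 7 an RNA-Pol2 summit, and of 19 histone genes none had either. Of 21230 protein-coding genes, 2690 had a wild type H3K27me3 summit at a promoter, 4614 an H3K27ac summit, 2192 an RNA-Pol2 summit and 11640 an Eed summit. Of the 39 Hox genes, 4 had an H3K27me3 summit within 1 kb of the start site, and 31 had an Eed summit.

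Wild type Eed lay at promoters of both kinds. At 2872 promoters with an H3K27me3 summit and no H3K27ac summit the median was 23.8 RPKM. It was 24.6 RPKM at 5011 promoters with an H3K27ac summit and no H3K27me3 summit, 28.4 RPKM at 672 promoters with both, and 2.03 RPKM at 35374 promoters without a summit in any library. Input had 11.8, 13.3, 13.7 and 7.85 RPKM at the same promoters. An Eed summit stood at 81.9% of the first group and 88.7% of the second. In the EedcKO Eed library the medians were 16.6, 14.9, 16.9 and 5.53 RPKM, beside 11.1, 12.1, 12.1 and 8.43 RPKM in its input.

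**Figure D1:**
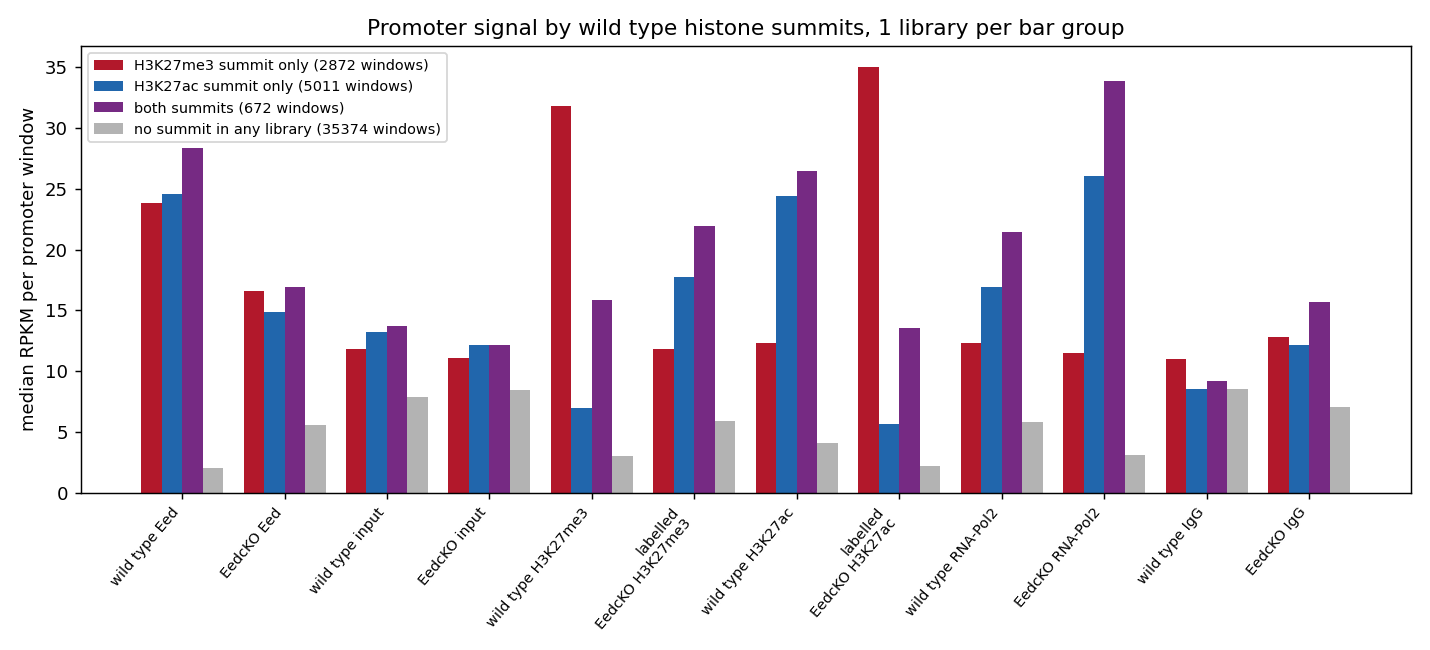
Median RPKM per promoter window (vertical axis) in each of the 12 libraries (horizontal axis), for promoters grouped by wild type histone summits; each bar is 1 library and has no error bar. The library labelled EedcKO H3K27ac reached 35.0 RPKM at promoters with only an H3K27me3 summit, close to the 31.8 RPKM of wild type H3K27me3, and 5.65 RPKM at promoters with only an H3K27ac summit.

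Eed signal changed in both directions between the libraries. Relative to the median promoter, 15217 of 50751 promoters were at least 2-fold lower and 11493 at least 2-fold higher in EedcKO. Genes are named from those whose higher library stood above its input, a filter that depends on the change itself. Syncrip, an RNA-binding protein gene (chromosome 9, 88481574 to 88483573), went from 234 to 22 counts (relative log2 ratio -3.76, interval -4.55 to -3.21). Other large decreases were at Usp9x, a deubiquitinase gene (195 to 18 counts, -3.77), Psma7, a proteasome subunit gene (346 to 35, -3.69), Ss18l1 (352 to 36, -3.67), Peg12, an imprinted gene (187 to 19, -3.64), and Elmo1 (317 to 34, -3.60). The windows of Psma7 (chromosome 2, 180041433 to 180043432) and Ss18l1 (180041509 to 180043508) overlap, so that both count the same reads.

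The other large decreases and all large increases rested on few reads. Olfr1093, Olfr1153, Klri2 and Olfr1157 had 19, 16, 15 and 12 counts in wild type and 0 in EedcKO, which makes them at least 8.55-, 7.20-, 6.75- and 5.40-fold lower relative to the median promoter. In input these 4 genes had 0 to 4 counts in wild type and 14 to 20 in EedcKO. The increases were at Kng2 (0 to 23 counts, at least 5.68-fold), Lpin1, a phosphatidate phosphatase gene (3 to 50, interval 2.00 to 5.95), and Xlr3a (0 to 16, at least 3.95-fold). They were also at Lgals12 (4 to 51), Sh3bp5l (6 to 66), Ubqln5 (4 to 49), Tspan32 (4 to 48), Acoxl (5 to 56), Bglap2 (1 to 23, interval 1.47 to 9.46) and Otos (7 to 70). Their wild type Eed counts lay below those of the wild type input, which ran from 8 to 31.

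Polycomb genes themselves had less Eed relative to the median promoter. Of the 14 measured PRC2 subunits 13 were at least 2-fold lower, with a median relative log2 ratio of -2.28 (interval -2.80 to -1.38), as were 17 of 19 PRC1 subunits (-2.27). Examples were Rbbp7 (181 to 20 counts, -3.53) and Ezh2, the methyltransferase of PRC2 (217 to 44, -2.70), and in PRC1 Bmi1 (293 to 43, -3.16) and Rnf2, its ubiquitin ligase (224 to 34, -3.10). Cdkn1c and Cdkn2a, inhibitors of the cell cycle, went from 297 to 48 (-3.03) and from 207 to 48 counts (-2.51), and 6 of 7 CDK inhibitors were lower (median -2.12).

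Lists of forebrain development also had medians below 0. Of 26 cortical progenitor genes 19 were lower and 4 higher (median -1.93), among them Sox3 (192 to 21, -3.54), Gli3 (242 to 42, -2.92) and Hes1 (258 to 46, -2.89). Of 29 cortical neuron genes 16 were lower (-1.49), with Sox11 going from 273 to 34 (-3.39) and Pou3f2 from 228 to 35 (-3.09). Of 18 neurogenic and intermediate progenitor genes 9 were lower and 1 higher (-1.01, interval -1.82 to 0.15, which includes 0), with Insm1 at 299 and 42 counts (-3.22), and of 26 ventral forebrain and interneuron genes 17 (-1.39), with Dlx2 at 177 and 38 (-2.61).

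Lists of regulators of other regions and tissues had medians below 0 as well. Lower were 25 of 35 midbrain, hindbrain and spinal cord regulators (median -2.09; Barhl1, 180 to 35 counts), 29 of 57 non-neural lineage regulators (-1.05; Twist1, 263 to 37). They were also 23 of 32 cortical hem, choroid plexus and secreted signal genes (-1.40; Bmp2, 243 to 48) and 23 of 39 Hox genes (-1.14; Hoxd13, 245 to 47). Among genes in general use, 14 of 20 housekeeping genes (-1.49; Vcp, 172 to 26) and 21 of 45 ribosomal protein genes (-0.91; Rpl7, 171 to 38) were lower. So were 10 of 19 histone genes (-1.0; H1f2, 94 to 24), 9 of 14 p53 targets (-1.45; Mdm2, 158 to 38) and 16 of 32 imprinted genes (-1.0, interval -1.65 to 0.45; Zdbf2, 190 to 45). Higher were 5 Hox, 8 imprinted, 6 ribosomal protein, 6 non-neural, 3 hem, 3 housekeeping, 2 midbrain, hindbrain and spinal cord, and 1 of the histone genes.

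These counts depend on the shift of the median. Without it, more members were higher than lower among Hox genes (11 and 8), imprinted genes (11 and 7), ribosomal protein genes (12 and 6) and neurogenic genes (5 and 3). Among random lists matched on Eed level, Hox genes lay at percentile 99.6, hem genes at 99.97 and neurogenic genes at 97.9, so that they were lowered less than promoters with as much Eed. Histone and receptor genes lay at 0. The PRC2, PRC1, CDK inhibitor, p53, cortical progenitor, cortical neuron, ventral forebrain, midbrain, non-neural, imprinted, ribosomal and housekeeping lists lay inside the central 95%, from 8.01 to 92.1. Matched on input, these 12 lists and the Hox and hem genes lay between 0 and 3.36, neurogenic genes at 29.4.

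Of the lists of cell types that are rare or absent at this stage, all but the oligodendrocyte list had a lower median of Eed counts than of input counts in wild type. Medians were 1.20 for astroglial genes (interval -0.35 to 1.72), 0.98 for microglia and macrophage genes (-0.31 to 1.52), 0.94 for endothelial genes (-0.79 to 1.59) and 0.62 for erythroid genes (-0.35 to 1.13), and all 4 intervals include 0. Median wild type counts were 11, 11, 15 and 7, beside 20, 22, 20.5 and 15 in wild type input. Matched on Eed level, these 4 lists lay at percentiles 97.7, 68.0, 94.5 and 83.5, and matched on input at 99.96, 96.7, 97.7 and 92.1. Medians were -0.59 for oligodendrocyte and -0.63 for mesenchyme and pericyte genes, both positive before the shift of the median was taken out; their wild type counts were 66 and 18, beside 21 in input for each. The 1711 olfactory and vomeronasal receptor genes tested had -1.15, from a median of 10 counts, and 143 of them had a library at 0; setting those at their bound left the median at -1.15.

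The split of changed promoters depended on scaling. Without a shift 23947 of 50751 promoters were higher and 7450 lower, and with both libraries scaled to the same median 5025 were higher and 20951 lower. With input subtracted they were 10000 and 9196, and with at least 20 reads 10097 and 5801. At the 1000 Polycomb promoters the median ratio lay 1.54 below other promoters on the log2 scale (-1.54, interval -1.62 to -1.44), less low than random lists matched on Eed level (central 95% from -1.82 to -1.72) and lower than those matched on input (-0.35 to -0.02). It was -2.47 at the 1000 genes ranked on Eed over input and -2.41 with input subtracted. That ranking uses the same pair of Eed libraries, so its value is not independent of the choice of genes.

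Before the histone comparisons, each EedcKO histone library was set against the wild type libraries of both marks. The reason was that the library labelled EedcKO H3K27ac held high counts at known Polycomb targets, with a median of 1804 at Hox genes. Low counts there in the library labelled EedcKO H3K27me3 (median 23) are what a loss of Eed would give under its label. Across the 1000 Polycomb promoters, the log2 RPKM of the library labelled EedcKO H3K27ac had a Pearson correlation of 0.985 with wild type H3K27me3 and of -0.22 with wild type H3K27ac. The library labelled EedcKO H3K27me3 had -0.15 with wild type H3K27me3, 0.709 with wild type H3K27ac and 0.823 with wild type RNA-Pol2. The set was ranked on the mean of both H3K27me3 libraries over IgG, which lowers the correlation between them by construction. Across all windows the same values were 0.736, 0.867 and 0.931. With EedcKO IgG the library labelled EedcKO H3K27me3 had 0.871 there, and EedcKO IgG itself had 0.888 with wild type RNA-Pol2. There the library labelled EedcKO H3K27ac had 0.936 with wild type H3K27me3 and 0.680 with wild type H3K27ac. Of the 10164 summits of the library labelled EedcKO H3K27ac, 55.5% lay within 500 bp of a wild type H3K27me3 summit and 3.99% of a wild type H3K27ac summit, against 0.480% and 0.359% after random shifts. Of the 671 summits of the library labelled EedcKO H3K27me3, 12.8% lay near wild type H3K27me3, 54.5% near wild type H3K27ac and 73.3% near wild type RNA-Pol2 summits. Directions drawn below for both marks and for RNA-Pol2 follow the labels as deposited. For RNA-Pol2 the label is open to doubt too. Across all windows the library labelled EedcKO RNA-Pol2 had 0.901 with wild type H3K27ac and 0.890 with wild type RNA-Pol2.

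**Figure D2:**
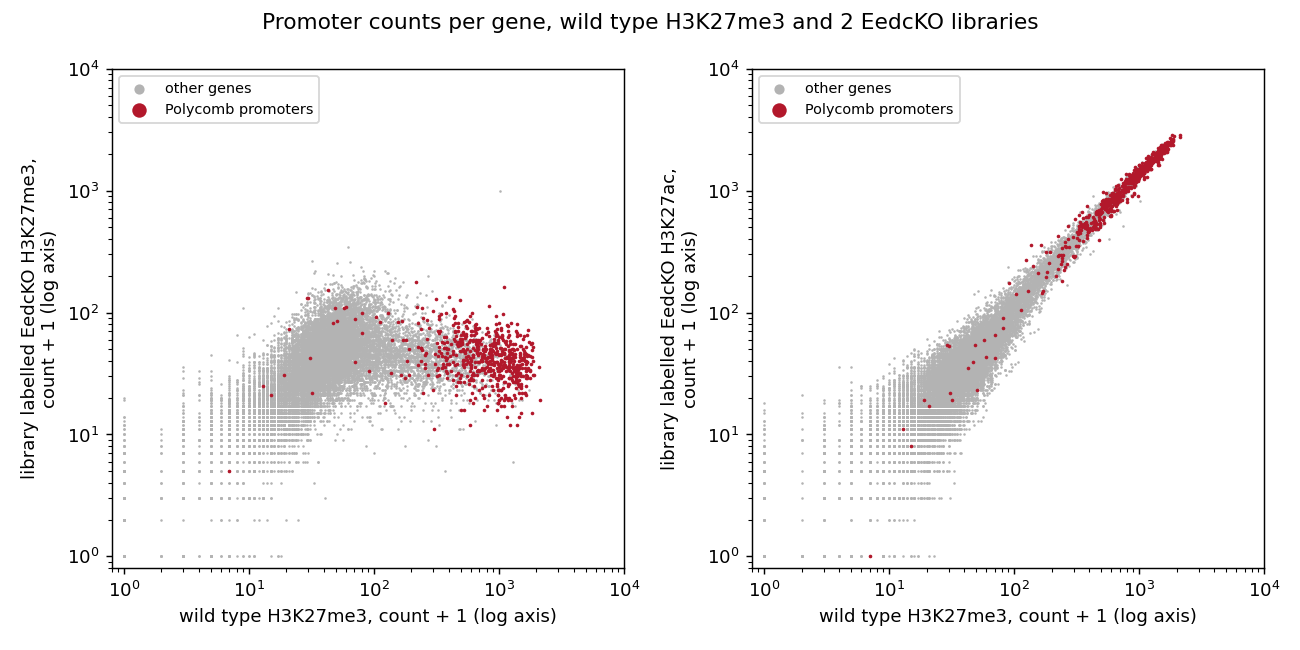
Promoter counts per gene plus 1 on log axes, wild type H3K27me3 (horizontal) against the libraries labelled EedcKO H3K27me3 (left) and EedcKO H3K27ac (right); each point is a gene and red points are Polycomb promoters. Red points follow the wild type H3K27me3 counts on the right (Pearson 0.985) and not on the left (-0.15). The choice of the red points lowers the value on the left by construction. Across all windows it was 0.736, against 0.936 on the right.

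Taken by its label, H3K27me3 at developmental regulators in EedcKO lay near the IgG count. All 39 Hox genes were at least 2-fold lower in the library labelled EedcKO H3K27me3, with a median of 1384 counts in wild type and 23 in EedcKO beside 29 in EedcKO IgG (relative log2 ratio -5.75, interval -5.87 to -5.46). Hoxb7 (chromosome 11, 96285623 to 96287622) went from 1300 to 5 counts (-7.55, interval -9.59 to -6.74), Hoxc9 from 1840 to 14 (-6.82), and Hoxa10 from 1397 to 11 (-6.73). Hoxd12 went from 2136 to 18 (-6.71), Hoxd11 from 1239 to 11 (-6.56) and Hoxb1 from 1527 to 18 (-6.23). The other largest decreases were at Evx1 (1462 to 13, -6.59), Foxb1 (1495 to 14, -6.52) and Tbx5, a heart and limb regulator (1160 to 13, -6.25). The EedcKO IgG library held 15 to 46 counts at these 9 promoters. In the library labelled EedcKO H3K27ac, Hoxb7 held 1696 counts.

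By label, regulators of other regions and lineages formed the lists with the lowest values. All 35 midbrain, hindbrain and spinal cord regulators (median -5.36; En1, 1344 to 19 counts; Pax2, 1911 to 30) and 49 of 57 non-neural lineage regulators (-5.10; Pax1, 1269 to 17) were lower. So were 25 of 26 ventral forebrain and interneuron genes (-4.37; Olig2, 986 to 17; Gsx2, 1232 to 30) and 30 of 32 cortical hem, choroid plexus and secreted signal genes (-4.24; Wnt10b, 1741 to 22; Lmx1a, 1535 to 30). Percentiles among random lists matched on H3K27me3 level were 0 for Hox genes, 0.01 for midbrain, hindbrain and spinal cord regulators, 0 for non-neural regulators, 12.6 for ventral forebrain and 8.66 for hem genes; matched on IgG all 5 were 0. Without the shift 39 Hox genes, 35 midbrain, hindbrain and spinal cord, 48 non-neural, 23 ventral forebrain and 29 hem genes were lower. The medians of these 5 lists against the library labelled EedcKO H3K27ac turned to 0.51, 0.54, 0.55, 0.60 and 0.56, with no Hox gene past 2-fold.

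By label, cortical genes divided. Of 26 cortical progenitor genes 18 were lower (median -2.16), led by Nr2f2 (592 to 11, -5.50), Dmrt3 (1077 to 34, -4.87), Pax6, a master regulator of cortical progenitors (chromosome 2, 105667900 to 105669899; 999 to 36, -4.68), and Emx1 (1370 to 70, -4.21). Of 18 neurogenic and intermediate progenitor genes 9 were lower (-1.14; Eomes, 778 to 24; Neurog1, 1314 to 48), as were 17 of 29 cortical neuron genes (-1.47; Fezf2, 646 to 19). Cdkn2a, whose product stops the cell cycle and stabilises p53, went from 1123 to 26 counts (-5.29), Cdkn2b from 568 to 38 (-3.79), and 4 of 7 CDK inhibitors were lower (-2.61, interval -5.29 to 0.42). With the library labelled EedcKO H3K27ac instead, the medians turned to 0.56 for cortical progenitor, 0.46 for neurogenic and 0.50 for cortical neuron genes and 0.22 for CDK inhibitors, with none of the 7 lower. The p53 targets had a median of 0.13, with Pmaip1 at 643 and 12 counts (-5.51).

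Lists of markers of other cell types and of several gene families had medians below 0. Medians were -2.11 for endothelial genes (interval -4.49 to 0.18; Flt1, 1458 to 30) and -1.44 for mesenchyme and pericyte genes (-5.37 to 0.47; Foxc1, 1444 to 24). They were -0.68 for astroglial, -0.60 for imprinted (Sfmbt2, 747 to 20), -0.42 for oligodendrocyte (Pdgfra, 689 to 22), -0.42 for erythroid, -0.23 for histone and -0.21 for microglia and macrophage genes, and -0.17 for PRC1 subunits (Bmi1, 296 to 22; Cbx8, 1086 to 97). The intervals of these lists include 0, except that of imprinted genes (-2.28 to -0.13). With the library labelled EedcKO H3K27ac instead, the medians turned to 0.24 for endothelial, 0.26 for mesenchyme, 0.26 for astroglial, 0.36 for oligodendrocyte, 0.24 for imprinted and 0.20 for histone genes and 0.11 for PRC1 subunits, and stayed below 0 for microglia and macrophage (-0.25) and erythroid genes (-0.11). The 1722 receptor genes tested had a median within 0.01 of 0, also with the 9 members at 0 in a library set to their bound. The astroglial, imprinted, oligodendrocyte, erythroid, histone, microglial, PRC1 and receptor lists had a positive median before the shift.

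The largest increases in the library labelled EedcKO H3K27me3 started from 3 to 61 wild type counts. Tmem126a went from 8 to 108 counts (3.35, interval 2.78 to 5.06), Polg2, a subunit of the mitochondrial DNA polymerase, from 31 to 262 (3.00), Romo1 from 33 to 217 (2.65), Nfs1 from 32 to 210 (2.64), Phykpl from 61 to 345 (2.49) and Kdm6a, an H3K27 demethylase gene, from 15 to 92 (2.42). The other 4 of the 10 largest increases were at Epn1 (7 to 65), Snapc5 (16 to 107), Tmem179b (23 to 145) and Tas2r116 (3 to 32). Housekeeping genes had a median of 0.52 (Actb, 47 to 149), ribosomal protein genes 0.44 (Rps27a, 23 to 97) and PRC2 subunits 0.81 (interval -0.94 to 1.29, with 5 of 14 higher and 2 lower; Rbbp4, 44 to 119), at percentiles 98.7, 99.5 and 99.97 of lists matched on H3K27me3 level. The medians of the same lists against the library labelled EedcKO H3K27ac were -0.08, 0.01 (interval -0.11 to 0.17) and 0.28 (-0.21 to 0.69).

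At Polycomb promoters the median H3K27me3 ratio lay at -4.35 against other promoters (interval -4.43 to -4.25), from 879.5 to 38 counts with 33 in EedcKO IgG, below the central 95% of matched random lists (-4.23 to -4.07). The set was ranked on the same pair of libraries. The ratio and its place among random lists are therefore not independent of the choice of the set. Against the library labelled EedcKO H3K27ac in place of the library labelled EedcKO H3K27me3, the direction turned, to 0.55; at the 1000 genes ranked on Eed over input it was -0.68, and with IgG subtracted -8.42. Without a shift, 20572 of 50165 promoters were higher and 3236 lower, and scaled to the same median 3743 and 6243. With IgG subtracted they were 10831 and 4648, and against the library labelled EedcKO H3K27ac 404 and 5203.

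Taken by its label, H3K27ac in EedcKO stood at the promoters that carried H3K27me3 in wild type. Otp, a hypothalamic regulator (chromosome 13, 94874602 to 94876601), held 0 counts in wild type and 1391 in the library labelled EedcKO H3K27ac, at least 509-fold more relative to the median promoter, and Hoxb8 (chromosome 11, 96280905 to 96282904) 0 and 1159, at least 424-fold more. Hoxd1 went from 3 to 1554 counts (interval 7.60 to 11.43), Hoxb7 from 4 to 1696 (8.30), Sim2 from 9 to 2864 (8.17), and Foxe1 from 8 to 2336 (8.01). Hoxa2 went from 7 to 1752 (7.75), Hoxc8 from 8 to 1824 (7.66), Tfap2a from 8 to 1780 (7.62) and Nkx2-2 from 10 to 2117 (7.61). EedcKO IgG held 20 to 49 counts at these 10 promoters.

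List medians by label were 6.78 for Hox genes (39 of 39 higher, with Hoxb8 at its bound 6.78 as well), 6.19 for midbrain, hindbrain and spinal cord regulators (35 of 35; Lbx1, 26 to 2747), 5.92 for non-neural lineage regulators (48 of 57; Foxa2, 18 to 1855). They were 4.79 for ventral forebrain and interneuron genes (25 of 26; Gsx1, 22 to 2068), 4.56 for hem, choroid plexus and secreted signal genes (30 of 32; Fgf8, 13 to 2033), 2.85 for CDK inhibitors (4 of 7; Cdkn2a, 28 to 1596). They were 2.76 for cortical progenitor genes (21 of 26; Otx2, 38 to 1330), 1.41 for cortical neuron genes (18 of 29; Lhx5, 48 to 2516) and 0.75 for neurogenic and intermediate progenitor genes (8 of 18; Eomes, 19 to 1146). Endothelial genes had 1.53 (Sox17, 24 to 1860), oligodendrocyte genes 1.13 (Sox10, 67 to 687), mesenchyme and pericyte genes 0.99 (Foxd1, 14 to 1831) and the 1331 receptor genes tested 0.75, also with the 13 members at 0 in a library at their bound. The median was lower for astroglial genes (0.44), imprinted genes (0.36; Ascl2, 44 to 1090), microglia and macrophage genes (0.22) and erythroid genes (0.08). The intervals of the CDK inhibitor (-0.54 to 5.88), neurogenic (-0.11 to 4.49), endothelial (-0.27 to 4.70), oligodendrocyte (-0.02 to 5.09), astroglial, imprinted, microglial and erythroid lists include 0. Among lists matched on H3K27ac level, Hox, non-neural and receptor genes lay at percentile 100, midbrain, hindbrain and spinal cord regulators at 99.98 and astroglial genes at 98.8. The other lists of this paragraph lay inside the central 95%, among them ventral forebrain (53.6), hem (57.1), and neurogenic genes (8.0).

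The Hox median against the library labelled EedcKO H3K27me3 was 0.49, that of midbrain, hindbrain and spinal cord regulators 0.22 and that of non-neural regulators 0.12. It was 0.10 for ventral forebrain and 0.09 for endothelial genes, and below 0 for CDK inhibitors (-0.02), hem (-0.16), mesenchyme (-0.17), oligodendrocyte (-0.25), cortical neuron (-0.28), cortical progenitor (-0.29) and neurogenic genes (-0.50). Astroglial genes had -0.41, microglial genes -0.24 and imprinted genes -0.004, while erythroid genes had 0.20 and receptor genes 0.79. Of the H3K27ac medians by label, those of neurogenic, astroglial, microglial, mesenchyme, erythroid, imprinted and receptor genes were negative before the shift.

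The largest decreases in the library labelled EedcKO H3K27ac started from 38 to 117 wild type counts. Mcts1 had 51 counts in wild type and 0 in EedcKO (at least 15.5-fold lower), Kdm5c, an H3K4 demethylase gene, 93 and 6 (-3.17, interval -5.30 to -2.64), Exo1 73 and 5 (-2.98), and Kcmf1 70 and 6 (-2.77). Dynlt1b had 40 and 2 (-2.76, interval -7.28 to -2.24), Mmgt1 61 and 5 (-2.73), Fkbp15 117 and 13 (-2.70), Gemin8 38 and 2 (-2.69, interval -7.21 to -2.16), Mettl14, an RNA methyltransferase gene, 66 and 6 (-2.68), and Brwd3 51 and 4 (-2.66). Subtraction of IgG turned the sign of Gemin8 and of Hprt (32 and 10 counts, -1.18). Ribosomal protein genes had a median of -0.90 (19 of 45 lower; Rpl32, 144 to 23), p53 targets -0.71 (2 of 14 lower and 2 higher; Btg2, 91 to 30), and housekeeping genes -0.57 (5 of 20 lower; Tbp, 61 to 9). The median was -0.56 for PRC2 subunits (4 of 14 lower and 2 higher; Eed, 130 to 35), -0.34 for histone genes (1 of 19 lower; H1f5, 64 to 23) and -0.20 for PRC1 subunits (5 of 19 lower and 6 higher). The intervals of the p53, PRC2, histone and PRC1 lists include 0. Matched on H3K27ac level, ribosomal protein genes lay at percentile 0.18 and the other 5 lists inside the central 95%, from 8.76 to 43.6. With the library labelled EedcKO H3K27me3 instead, the medians were -0.44 for ribosomal protein genes (9 of 45 lower), -0.52 for p53 targets, -0.20 for housekeeping genes, -0.07 for PRC2 subunits, -0.48 for histone genes and -0.38 for PRC1 subunits.

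The median ratio of H3K27ac at Polycomb promoters was 5.03 above other promoters (interval 4.89 to 5.15), from 36 to 1216 counts, above the central 95% of matched random lists (4.60 to 4.77). Against the library labelled EedcKO H3K27me3 it was 0.19, at the genes ranked on Eed over input 0.73, and with IgG subtracted 10.2. Without a shift 3793 of 47998 promoters were higher and 24764 lower, and scaled to the same median 8826 and 5678. They were 7658 and 2117 against the library labelled EedcKO H3K27me3, and with IgG subtracted 3604 and 13629.

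**Figure D3:**
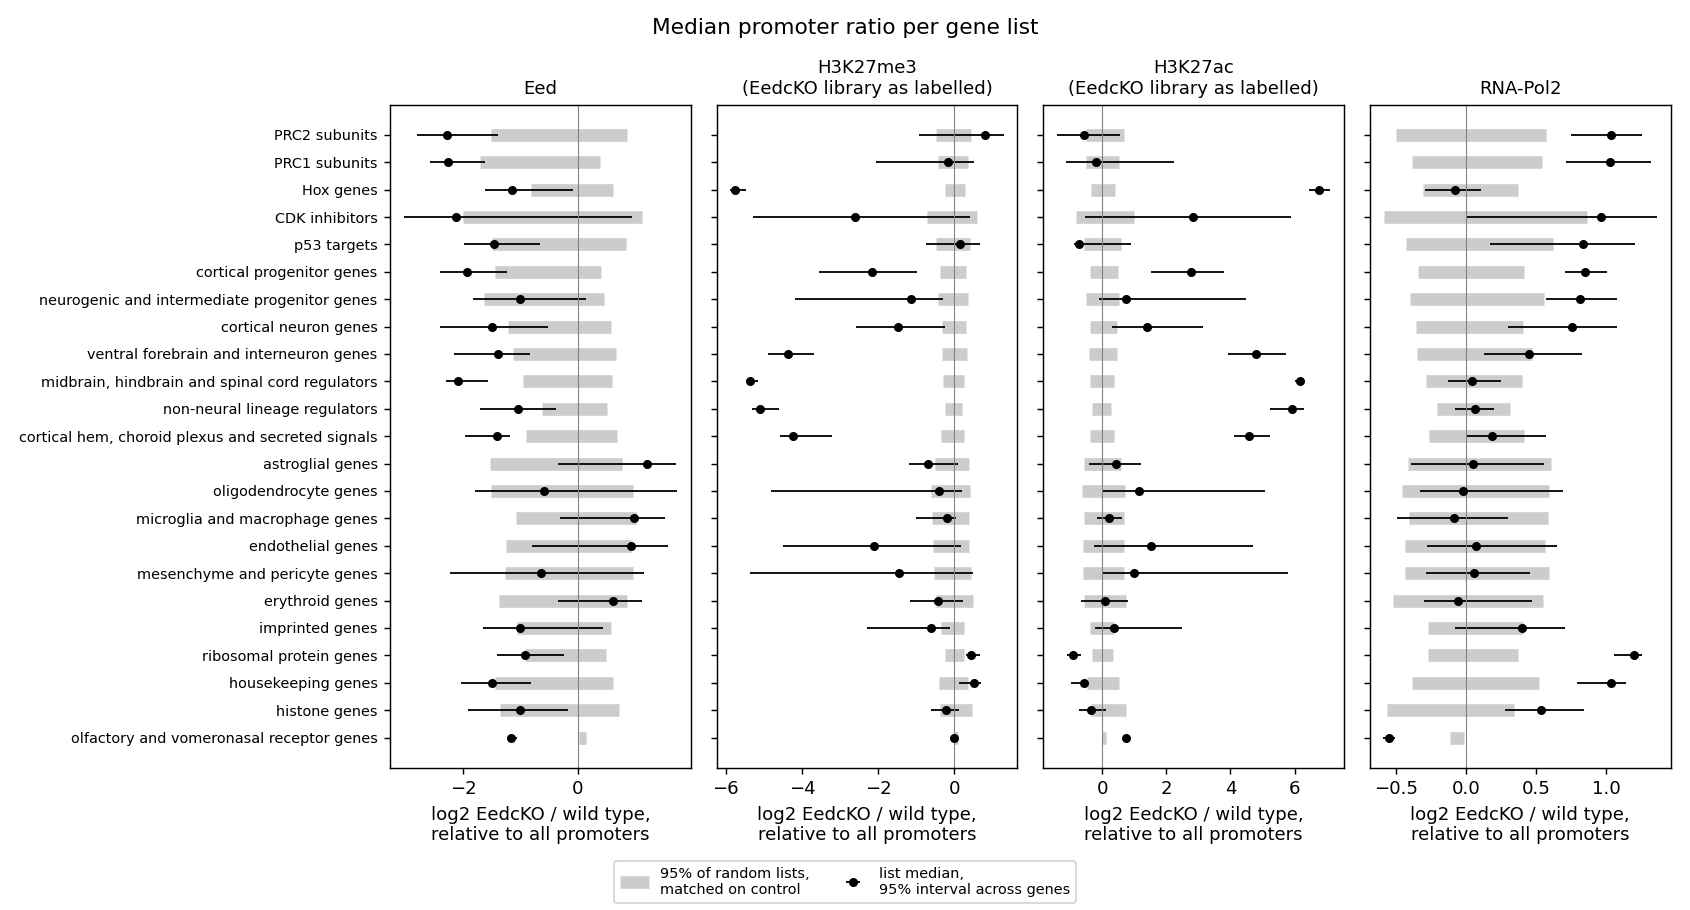
Median relative log2 ratio of EedcKO to wild type for each gene list (points, with 95% order-statistic intervals across genes) and each target, beside the central 95% of random lists matched on the control libraries (grey bars). Hox genes lie at -5.75 for H3K27me3 and 6.78 for H3K27ac by label, and ribosomal protein genes at 1.20 for RNA-Pol2; without the shift of all promoters 2 of 23 medians for Eed, 8 for H3K27me3, 7 for H3K27ac and 7 for RNA-Pol2 changed sign.

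RNA-Pol2 signal by label had a median of 16.9 RPKM in wild type and 26.0 RPKM in EedcKO at promoters with only an H3K27ac summit. At promoters with only an H3K27me3 summit it had 12.3 and 11.5 RPKM, and at promoters without a summit 5.84 and 3.12 RPKM. Relative to the median promoter, 6146 of 50379 promoters were at least 2-fold higher and 3958 at least 2-fold lower in EedcKO. Emx2, a regulator of cortical area identity and a Polycomb promoter (chromosome 19, 59457372 to 59459371), went from 16 to 138 counts (2.72, interval 2.14 to 3.74). Cortical progenitor genes had a median of 0.85 (8 of 26 higher), with Gli3 at 57 and 256 counts (1.91), Id4 at 50 and 188 (1.65) and Hes5, a Notch target, at 57 and 211 (1.63). The other large increases were Slc33a1 (23 to 149, 2.37), Zcchc3 (12 to 85), Cops2 (26 to 158, 2.29) and Dynlt1b (6 to 64, 2.78). Wild type IgG held 17 counts at Emx2, 22 at Slc33a1, 18 at Zcchc3 and 10 at Dynlt1b, so their wild type RNA-Pol2 counts lay near or below IgG. At Cops2 it held 5.

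Further increases fell in a zinc finger family on chromosome 13. Zfp729b and Rsl1 had 0 counts in wild type and 55 and 46 in EedcKO, at least 15.8- and 13.2-fold more relative to the median promoter, and Zfp729a had 4 and 57, Zfp85 5 and 41 and Zfp456 4 and 34. In IgG the same 5 genes ran the other way, with 10, 13, 20, 28 and 30 counts in wild type and 0, 3, 4, 6 and 2 in EedcKO, in the order Zfp729b, Rsl1, Zfp729a, Zfp85, Zfp456. The largest decreases were also in gene families with few reads: Dcpp1 and Dcpp2, with the same counts, 23 and 0 (at least 8.92-fold lower), Olfr320 and Serpina1a with 20 and 0 (at least 7.76-fold), and Serpina3g with 38 and 4 (-2.59). Vmn2r91 had 17 and 0 (at least 6.60-fold), Serpina1d 15 and 0 (at least 5.82-fold), Olfr313 30 and 4 (-2.27), and Serpina1c and Trim43c 13 and 0 (at least 5.04-fold).

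Genes in general use and Polycomb genes had the highest RNA-Pol2 list medians by label, relative to the median promoter. For RNA-Pol2, no list median was taken against another EedcKO library. Ribosomal protein genes had 1.20 (31 of 45 higher; Rps9, 48 to 170; Rplp0, 62 to 210), PRC2 subunits 1.03 (9 of 14; Suz12, 71 to 241; Ezh2, 93 to 261), housekeeping genes 1.03 (11 of 20; Gapdh, 148 to 461), and PRC1 subunits 1.03 (10 of 19; Yaf2, 33 to 149). CDK inhibitors had 0.96 (3 of 7; Cdkn2c, 37 to 106; Cdkn1b, 102 to 268), p53 targets 0.83 (5 of 14; Sesn2, 97 to 310), and neurogenic and intermediate progenitor genes 0.81 (5 of 18; Dll3, 68 to 214). Cortical neuron genes had 0.75 (11 of 29; Sox4, 64 to 200; Bcl11b, 37 to 106), histone genes 0.53 (2 of 19; H4f16, 55 to 134), ventral forebrain and interneuron genes 0.45 (4 of 26; Meis2, 46 to 136) and imprinted genes 0.40 (4 of 32; Zdbf2, 33 to 121). Without the shift few members were higher: 4 ribosomal protein genes, 1 PRC2 subunit, 3 PRC1 subunits, 2 p53 targets, 4 cortical progenitor genes, 1 each of the histone, ventral forebrain and imprinted genes, and none of the housekeeping, CDK inhibitor, neurogenic and cortical neuron genes. Percentiles among lists matched on RNA-Pol2 level were 100 for ribosomal protein genes, 99.95 for histone genes and 98.0 for PRC1 subunits, and 72.5 to 94.8 for the other 8 of these lists.

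Regulators of other regions stayed near the median. Hox genes had -0.08, with none of 39 past 2-fold (Hoxa3, 40 to 48), midbrain, hindbrain and spinal cord regulators 0.05 (none of 35; Tlx3, 98 to 86), non-neural lineage regulators 0.07 (1 of 57 higher and 1 lower; Gata6, 82 to 111) and hem, choroid plexus and secreted signal genes 0.19 (3 of 32 higher; Foxj1, 94 to 245). Endothelial genes had 0.07, mesenchyme and pericyte genes 0.06, astroglial genes 0.05, oligodendrocyte genes -0.02, erythroid genes -0.06, and microglia and macrophage genes -0.09. The 1741 receptor genes tested had -0.55, also with the 10 members at 0 in a library at their bound. The positive medians of 0.40 and below were negative before the shift.

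At Polycomb promoters the median RNA-Pol2 ratio lay 0.43 above other promoters (interval 0.38 to 0.47), above the central 95% of matched random lists (0.29 to 0.40), from 55.5 to 84 counts beside 22 and 33 in IgG; subtraction of IgG turned it to -0.27. It was 0.87 at the genes ranked on Eed over input. Without a shift 1219 of 50379 promoters were higher and 10655 lower, and scaled to the same median 9899 were higher and 2428 lower. With IgG subtracted the numbers were 4866 and 4139.

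Summits differed in number between genotypes for each target. Eed had 61019 in wild type and 39351 in EedcKO, of which 32191 and 63 had a score of at least 10. H3K27me3 had 10662 in wild type against 671 in the library labelled EedcKO H3K27me3, H3K27ac 8229 against 10164 in the library labelled EedcKO H3K27ac, and RNA-Pol2 3716 against 25930. Of the wild type summits, 7.38% (interval 7.18 to 7.59) for Eed, 0.807% (0.654 to 0.995) for H3K27me3, 4.93% (4.49 to 5.42) for H3K27ac and 74.8% (73.3 to 76.1) for RNA-Pol2 had an EedcKO summit of the same label within 500 bp. By the other label, 52.95% of wild type H3K27me3 summits lay near a summit of the library labelled EedcKO H3K27ac (52.0 to 53.9), and 4.46% of wild type H3K27ac summits near one labelled EedcKO H3K27me3 (4.03 to 4.93). For the same labels, the highest of 100 random shifts gave 1.77%, 0.0657%, 0.705% and 1.91%. Wild type Eed summits lay near H3K27me3 in 5.59%, near H3K27ac in 6.80% and near RNA-Pol2 in 3.25%, against 0.431%, 0.333% and 0.155% after shifts. In the other direction, 31.0% of wild type H3K27me3, 48.9% of H3K27ac and 50.7% of RNA-Pol2 summits had an Eed summit near. Of EedcKO Eed summits, 0.264% lay near a summit of the library labelled EedcKO H3K27me3 and 3.48% near one labelled EedcKO H3K27ac. After shifts these shares were 0.0286% and 0.434%, since the lists hold 671 and 10164 summits.

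More active promoters had an RNA-Pol2 summit in EedcKO by label. Summits were called in each library by itself, and promoter totals were 2482297 in wild type RNA-Pol2 and 3842779 in EedcKO RNA-Pol2. The EedcKO RNA-Pol2 library had a summit at 88.9% of the 5011 promoters with only a wild type H3K27ac summit, where wild type RNA-Pol2 had one at 31.8%, and at 29.9% against 3.76% of the 2872 promoters with only an H3K27me3 summit. Of the 21230 protein-coding genes, 8558 had an EedcKO RNA-Pol2 summit at a promoter against 2192 in wild type. Of the lists, 43 of 45 ribosomal protein genes had an EedcKO RNA-Pol2 summit against 12 in wild type, 17 against 3 of 26 cortical progenitor genes, 13 against 3 of 29 cortical neuron genes, 12 against 2 of 14 PRC2 subunits, and none of 39 Hox genes in either.

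Ratios of the targets were compared across genes, which are not independent replicates, in 6 relations. The ratios of H3K27me3 and H3K27ac by label had a Pearson correlation of -0.718 across 47844 genes (Spearman -0.418). Eed and RNA-Pol2 had -0.300 (Spearman -0.294), H3K27ac and RNA-Pol2 -0.183 (-0.292), Eed and H3K27me3 0.0661 (-0.0162), Eed and H3K27ac -0.0583 (0.0183), and H3K27me3 and RNA-Pol2 0.00779 (0.0707). At 3216 promoters at least 2-fold lower in the library labelled EedcKO H3K27me3 without the shift, the median relative RNA-Pol2 ratio was 0.28 (interval 0.26 to 0.30), against 0.23 (0.20 to 0.26) in matched promoters that were not lower. The matched difference was 0.05 for RNA-Pol2, 2.23 for the library labelled EedcKO H3K27ac and 0.29 for Eed, where the ratios were -1.24 and -1.53. With promoters chosen relative to the median, it was 0.10, 2.26 and 0.16. The library labelled EedcKO H3K27ac had the promoter profile of wild type H3K27me3 (Pearson 0.936 across all windows). A like profile thus enters the H3K27me3 ratio as denominator and the H3K27ac ratio as numerator. The correlation of -0.718 and the differences of 2.23 and 2.26 can follow from this alone.

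Across all windows, input had a Pearson correlation of 0.889 between genotypes on the log2 scale (Spearman 0.609) and IgG 0.854 (0.628). Chromosome X promoters of coding genes had 0.522 of the autosomal median in wild type input and 0.5 in EedcKO input, and 0.462 and 0.412 in IgG. In Eed the values were 0.243 and 0.395. The chromosome Y genes Ddx3y, Kdm5d, Eif2s3y and Uty were summed, without scaling to totals. They held 16 counts in wild type and 36 in EedcKO input, and 27 and 44 in IgG. In Eed they held 12 and 38, in H3K27me3 39 and 63, in H3K27ac 57 and 29, and in RNA-Pol2 54 and 149. A difference in sex was not tested. Among the named genes, Usp9x, Xlr3a, Rbbp7, Sox3, Hprt, Kdm6a, Mcts1, Kdm5c, Mmgt1, Gemin8 and Brwd3 lie on chromosome X. EedcKO IgG had 40 counts at promoters with only an H3K27me3 summit and 22 at promoters without summits, and wild type IgG 31 and 24.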

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

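The minimum of 20 reads and the comparisons with the library of the other label were chosen after the data were seen. No paired analysis was possible because each genotype had 1 library per target. Over all alternatives, the results of the main comparisons stayed within their interval, or within 1.5 times for counts, in 47 of 112 cases, moved in 56 and changed direction in 9; a count of changed promoters changed direction when most went the other way. Gene list medians did so in 279, 29 and 14 of 322 cases, and named genes in 1140, 270 and 2 of 1412. Values of lists and named genes are relative to the median promoter, so scaling to the same median hardly moves them by construction. That setting gave 88 of the 279 and 353 of the 1140. Causes were not tested unless given. Depth limits the low promoters most, since 1 read was worth up to 0.527 RPKM.

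Subtraction of the control library gave 19196 changed promoters for Eed, 15479 for H3K27me3 and 17233 for H3K27ac, with fewer promoters tested, and 9005 for RNA-Pol2 with the direction turned (4866 higher and 4139 lower). At Polycomb promoters it gave -2.41 for Eed, -8.42 for H3K27me3, 10.2 for H3K27ac and, with the sign changed, -0.27 for RNA-Pol2; the cause was not tested. For H3K27ac by label, Gemin8 turned to 0.0864 and Hprt to 0.0359; the cause was not tested. A minimum of 20 reads left 15898 changed Eed promoters, from fewer promoters tested. Scaling to the same median shifts all ratios of a target together by construction, and the counts of all 4 targets turned, which are 4 of the 9. It gave 25976 changed promoters for Eed (5025 higher and 20951 lower, from 23947 and 7450), 9986 for H3K27me3 (3743 and 6243, from 20572 and 3236), 14504 for H3K27ac (8826 and 5678, from 3793 and 24764) and 12327 for RNA-Pol2 (9899 and 2428, from 1219 and 10655).

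Against the library labelled EedcKO H3K27ac, 5607 promoters changed from wild type H3K27me3, mostly lower, and the Polycomb value turned to 0.55. Against the library labelled EedcKO H3K27me3, 9775 changed from wild type H3K27ac, mostly higher, and the Polycomb value was 0.19. Gene list medians that turned from a by-label interval that excluded 0 were, for H3K27me3, Hox (0.506), midbrain, hindbrain and spinal cord (0.538), non-neural (0.551), ventral forebrain (0.599), hem (0.562), cortical progenitor (0.564), neurogenic (0.463), cortical neuron (0.504), imprinted (0.242) and housekeeping genes (-0.0766). The CDK inhibitor, endothelial, mesenchyme, astroglial, oligodendrocyte, histone and PRC1 medians changed sign too, but their by-label intervals include 0. For H3K27ac they were cortical progenitor (-0.287), cortical neuron (-0.282), hem (-0.162) and mesenchyme genes (-0.171). The CDK inhibitor, oligodendrocyte, neurogenic, astroglial, microglial and imprinted medians changed sign too, from by-label intervals that include 0. A different library enters each by construction.

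Polycomb values with pseudocounts of 0.1 and 1 RPKM were -1.68 and -1.42 for Eed, -4.47 and -4.20 for H3K27me3, and 5.20 and 4.84 for H3K27ac. Without a filter on low RPKM, Eed had -1.44 and RNA-Pol2 0.36. With the top 500 and the top 2000 genes, H3K27me3 had -4.78 and -3.65, H3K27ac 5.55 and 4.18, and RNA-Pol2 0.37 and 0.52. Ranked on Eed over input, Eed had -2.47, from a ranking that uses the same Eed libraries. In this ranking H3K27me3 had -0.68, H3K27ac 0.73 and RNA-Pol2 0.87. The cause of these values was not tested.

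A score of at least 10 left 32191 wild type and 63 EedcKO Eed summits, 4220 and 73 for H3K27me3, 845 and 4608 for H3K27ac, and 667 and 6715 for RNA-Pol2. With this score, the share of wild type summits near an EedcKO summit of the same label was 0.0528% for Eed, 0.0474% for H3K27me3, 1.07% for H3K27ac and 91.3% for RNA-Pol2. Within 250 and 1000 bp it was 4.55% and 11.5% for Eed, 3.28% and 6.06% for H3K27ac, and 59.8% and 83.7% for RNA-Pol2. Within 1000 and 5000 bp, wild type Eed summits lay near wild type H3K27me3 in 8.27% and 14.1%, and EedcKO Eed summits near the library labelled EedcKO H3K27me3 in 0.417% and 1.01%; a wider distance takes in more summits by construction.

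With a pseudocount of 1 RPKM, the correlation across genes was -0.331 for Eed and RNA-Pol2, -0.749 for H3K27me3 and H3K27ac, 0.0320 for H3K27me3 and RNA-Pol2, and -0.195 for H3K27ac and RNA-Pol2. With a mean RPKM of at least 0.5 it was -0.068 for Eed and H3K27ac, -0.285 for Eed and RNA-Pol2, -0.684 for H3K27me3 and H3K27ac, and -0.196 for H3K27ac and RNA-Pol2.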

Other observations

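The comparison of single genes between the library labelled EedcKO H3K27ac and wild type H3K27me3, the test of an H3K27ac gain, the test of Eed at active promoters and the test of RNA-Pol2 background were chosen after the results were seen.

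Set against wild type H3K27me3, 99.3% of the 1000 Polycomb promoters in the library labelled EedcKO H3K27ac lay within 2-fold of their own median ratio. The 8 highest protein-coding genes were H2-Q6, from 137 counts in wild type H3K27me3 to 359 (log2 0.92 above the Polycomb median, interval 0.65 to 1.23), Zar1 (123 to 271, 0.67), Cdk6 (164 to 360, 0.67), Prdm16 (381 to 743, 0.50), Sox2 (267 to 511, 0.47), Rfx4 (515 to 978, 0.47), H2-K1 (307 to 582, 0.46) and Sox1 (351 to 662, 0.46). The 8 lowest were Sprr2a3 (6 to 0), Ywhaq (50 to 22), H2bu2 (70 to 41), Bex3 (14 to 7), H3f3b (31 to 18), Hp1bp3 (59 to 42), Med13l (30 to 21) and Nr2f1 (239 to 181). The 13 cortical progenitor genes of the set had a median of 0.05 (interval -0.25 to 0.30), inside the random lists (percentile 90.3). The 35 Hox genes of the set had a median of -0.04, below the central 95% of random lists (-0.02 to 0.06), and 19 ventral forebrain and interneuron genes had 0.07 (interval -0.03 to 0.14), at percentile 97.8. Chromosome X held 1528 of the 61019 wild type Eed summits and 106 of the 39351 EedcKO Eed summits.

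The library labelled EedcKO H3K27ac had the promoter profile of wild type H3K27me3. A gain of H3K27ac under right labels is argued against, since its contrast over IgG at promoters with only an H3K27ac summit was 0.159 of that in wild type H3K27ac (interval 0.149 to 0.167). Loss of H3K27me3 down to the IgG background in the library labelled EedcKO H3K27me3 is argued against too, since its log2 ratio over IgG was 0.74 higher at promoters with an H3K27ac summit than at promoters without summits (0.72 to 0.76). At promoters with only an H3K27me3 summit it was 0.11 higher, as a loss would give there, and untargeted cutting stronger than in IgG stays open. Exchanged labels are a candidate explanation: summits of the library labelled EedcKO H3K27me3 lay near wild type H3K27ac more often than near wild type H3K27me3, by 41.7 percentage points (37.7 to 46.1). This library had only 671 summits against 8229 in wild type H3K27ac. Its contrast of 0.74 was also small beside 2.28 in wild type H3K27ac, taken at promoters with only an H3K27ac summit. Untargeted cutting at active promoters could place summits there too, so the share does not single out an exchange. A rotation that also involves RNA-Pol2 cannot be told apart from an exchange. Of the 671 summits of the library labelled EedcKO H3K27me3, 73.3% lay near wild type RNA-Pol2 against 54.5% near wild type H3K27ac. Across all windows this library had a Pearson correlation of 0.931 with wild type RNA-Pol2 and of 0.867 with wild type H3K27ac (Spearman 0.877 and 0.847). With EedcKO IgG it had 0.871 (Spearman 0.741), and EedcKO IgG itself had a Pearson correlation of 0.888 with wild type RNA-Pol2. High Pearson values across all windows therefore do not by themselves show an active mark. The library labelled EedcKO RNA-Pol2 had 0.890 with wild type RNA-Pol2 and 0.901 with wild type H3K27ac (Spearman 0.882 and 0.903). The test set for a rotation gave values between its bounds (Spearman -0.12 across 5635 promoters and 0.068 after IgG and mean level were taken out). A wrong genotype or an outside sample was not tested. Under an exchange, H3K27me3 at Polycomb promoters would not have been lower in EedcKO relative to other promoters. Each library was scaled to its own total, so a loss shared by all promoters would not show in these ratios.

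Wild type Eed signal stood at promoters with H3K27ac and without H3K27me3. Background of open promoters as the whole cause was tested by the log2 contrast with promoters without summits. This contrast was 3.31 in wild type and 1.35 in EedcKO, while input had 0.72 and 0.50. Their ratio in Eed was 0.407 (interval 0.404 to 0.419), past the bound set against this cause. The reference promoters had no summit in any library, wild type Eed included, which can enlarge the wild type contrast. Their medians were 2.03 RPKM in wild type Eed and 5.53 RPKM in EedcKO Eed. The interval does not cover this choice. At the active promoters the medians were 24.6 and 14.9 RPKM, so the reference differed by a larger factor between the libraries than the active promoters did. The ratio therefore cannot decide whether background is the whole cause. A lower yield of the EedcKO immunoprecipitation could give the same ratio and stays open, as does binding of Eed at these promoters, which remains a hypothesis.

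The EedcKO RNA-Pol2 library had more summits than the wild type library. If a single difference in signal over background were the cause, promoters with an H3K27me3 summit should lie on the line that relates both libraries at other promoters. Their median residual was 0.28 (interval 0.25 to 0.30, 3541 promoters), between the bounds set. It joins 2 parts: 0.19 at promoters with only an H3K27me3 summit, inside the bound of 0.25, and 0.54 at promoters with both summits, past the bound of 0.5. Promoters with only an H3K27ac summit had 0.67 although the line was fitted to them, so a straight line does not describe active promoters, and such a difference cannot be told apart from a change in RNA-Pol2. A biological difference between the genotypes stays open and was not tested.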
